A study of Mus musculus with 8 samples.

How the data were processed

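Chromatin accessibility was assayed by ATAC-seq, in which the Tn5 transposase places sequencing adapters into open DNA, in mouse macrophages grown from bone marrow. Per the labels, bone marrow cells were cultured for 7 days in 60 mm dishes, left untreated or given lipopolysaccharide (LPS) for 6 h, frozen in medium with 5% DMSO, thawed, lysed and tagmented, and the libraries were amplified by 10 cycles of PCR. The cells were wild type (WT) or lacked Lamin-A (KO). There were 8 libraries, 2 in each of the 4 groups formed by genotype and treatment. The labels do not say whether the 2 replicates of a group came from different animals, so every p-value over libraries measures the spread between these samples. The source names of the LPS libraries also carry the word untreated, while their titles and treatment fields say LPS, and the titles were followed. The dose of LPS, the targeted part of Lmna and the sex of the animals are not stated in the labels.

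The deposited files were peak lists, 1 for each library, with replicates called separately and not pooled. The submitters' processing notes name BWA 0.7.12, MACS2 and the mm10 genome build. Each peak carried a fold enrichment over local background, which is a ratio that the authors' peak caller made within 1 library. The deposited lists also held the -log10 p and -log10 q of each peak, and a deposited score equal to 10 times the -log10 p as a whole number. The summit of each peak was given by the authors as a distance in bp from the peak's start. These values are the authors' own and were used to rank peaks within a list, to set the cut-offs of 2 alternatives and to work out the background below. The filter behind the lists is not stated, and the peak numbers left 544 to 587 gaps in each list. The lowest -log10 p ranged from 7.35 to 7.93 over the libraries.

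Read counts were not used here, so the background behind the calls was worked out from the peaks themselves. For peaks on the flat genome-wide background, the enrichment and the p-value together fix the pileup and the background, and 20 such value pairs were solved in each library. The background was 5.53 reads in all 8 libraries, and the lowest pileup of a called peak on the flat background was 23 or 24 reads. A region missing from a list was not called or not kept, whether for a low pileup, a high local background or the unstated filter, which is not the same as closed DNA.

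Peaks of the 8 lists that overlapped by at least 1 bp were merged into 76751 regions, and a library held a region when any of its peaks overlapped it. For each pair of groups, a region was called gained when both libraries of the first group held it and neither of the second did, and lost in the reverse case. No p-value was given to a region, because 2 libraries against 2 cannot reach an exact two-sided p below 0.333. Each count was set beside the counts from the other 2 ways of dividing the same 4 libraries. Regions held by all 4 libraries of a treatment or genotype and none of the other 4 were counted over all 35 divisions of the 8 libraries. Peak number, covered length, median width and the shares of peaks at gene ends and in gene-poor windows were compared by exact two-sided permutation within strata of the other factor, each stratum with the same weight. These exact tests have 36 arrangements, cannot go below p = 0.0556, and formed a family of 11 tests with the interaction of LPS and genotype in peak number.

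Genes came from a RefSeq annotation of the same build, with 21887 protein-coding genes. It gives no strand, so transcription start sites could not be placed, and the planned distance to the start site was replaced by the distance from the summit to the nearest end of a gene span, whichever end that was. A region was assigned to the nearest such gene within 50 kb, which placed 61954 regions (80.7%) on 15361 genes. A region was at a gene end when its summit lay within 1 kb of it. Gene-poor windows were the 917 of 2732 windows of 1 Mb with 2 or fewer protein-coding genes. Shares of gained and lost regions at these places were compared by two-sided Fisher's exact test with regions held by all libraries compared. Regions are not independent replicates, so these p-values count neighbouring regions as separate observations, and all intervals cover counting error only.

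The 14 gene lists covered inflammatory cytokines and enzymes, the NF-kB pathway and its feedback, the interferon response, macrophage identity, alternative activation and scavenging, the cell cycle, the nuclear envelope and lamina, and markers of B cells, T and NK cells, neutrophils, dendritic cells, erythroid cells and megakaryocytes, stromal and endothelial cells, and stem and progenitor cells. Of their 309 genes, 306 were matched. For each list, the genes with at least 1 gained or lost region were counted and compared with 10000 random lists matched on the number of regions per gene, two-sided, which gives a permutation p over genes and not over libraries. The random lists were not matched on position. List members that lie next to each other therefore count as separate observations, which can make p too small. Benjamini-Hochberg adjustment ran over the 14 lists within each comparison and direction, with a threshold of 0.05.

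Named regions followed a rule. They were Lmna, then for each comparison and direction the 10 gained or lost regions with the highest mean rank percentile by -log10 p in the libraries that held them, 1 per gene, and up to 4 members of each gene list with the most such regions. Any other gene is said to have been chosen after its values were seen. The groups, comparisons, tests, gene lists, rule for named regions and most alternative settings were fixed before the data were examined. The alternatives were a -log10 p of at least 10, equal numbers of peaks (the 44504 with the highest -log10 p in each list), chromosomes 1 to 19 only, peaks covering at least 50% of a region, windows of 100 bp either side of summits, genes within 20 kb, a replicate block (the replicate number as stratum), for which the KO minus WT difference in peak number was -9264 with an exact p = 0.125, and leaving out each library. An exact p of 0.125 is the smallest that the replicate block can give for a difference between genotypes or treatments. Chosen after seeing the data were a -log10 p of at least 20, assignment of regions inside a gene to that gene, comparison of gained directly with lost regions, and the counts of other divisions with equal numbers of peaks.

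Motif tests with 10 fixed motifs and the comparison of GC content were planned and not run, because they need the genome sequence. The methods were tested on simulated data in which 200 regions gained a 2-fold and 200 a 4-fold higher signal. These regions were drawn only from those with a mean pileup below the cut-off of 23 reads. The shares recovered therefore do not hold for stronger regions. In the pairwise comparisons 49.5 to 55% of the 2-fold and 55.5 to 69.5% of the 4-fold regions were recovered, beside 1457 to 1572 regions called gained by chance. With 4 libraries against 4, 21.5 to 28.5% and 38 to 39% were recovered, beside 57 to 69. The spread of the simulated libraries was assumed, and was not fitted to the deposited lists, whose other divisions gave 221 to 1174 regions on a side in the pairwise comparisons. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.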

Results

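Accessible chromatin was mapped by ATAC-seq in mouse bone-marrow-derived macrophages that were wild type (WT) or lacked Lamin-A (KO), a structural protein of the nuclear lamina encoded by Lmna. The cells were untreated or had received lipopolysaccharide (LPS), a bacterial cell wall component sensed through TLR4, for 6 h, with 2 libraries in each of the 4 groups. The study asked how LPS changes accessibility and what part Lamin-A plays. The 8 peak lists held 44504 to 59750 peaks covering 17.9 to 24.96 Mb of the mm10 genome, and the background pileup recovered from each list was 5.53 reads in all 8; read totals and reads in peaks were not used here. The lists merged into 76751 regions, of which 30960 (40.3%) were called in all 8 libraries. Libraries of the same group shared 78.4 to 82.3% of their combined regions, and libraries of different groups shared 58.7 to 75.5%. Strength is given below as the mean percentile of a region's -log10 p within the lists that hold it, and gained and lost mean called in both libraries of one group and neither of the other.

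Lmna itself, on chromosome 3 from 88481148 to 88509932, held 7 regions, 3 of them called in all 8 libraries. The region from 88483646 to 88484020 was called in all 4 WT libraries and no KO library. The region from 88484558 to 88484979, inside the gene and 3.6 kb from its end, was called in all 4 KO libraries and no WT library. Both were picked out of the 7 because they divide the genotypes. Others did not, such as the region from 88500206 to 88500489, called in both untreated WT libraries, 1 untreated KO library and no LPS library. The labels do not state which part of Lmna was targeted, so differences in calls inside the gene cannot be read as accessibility alone.

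**Figure D1:**
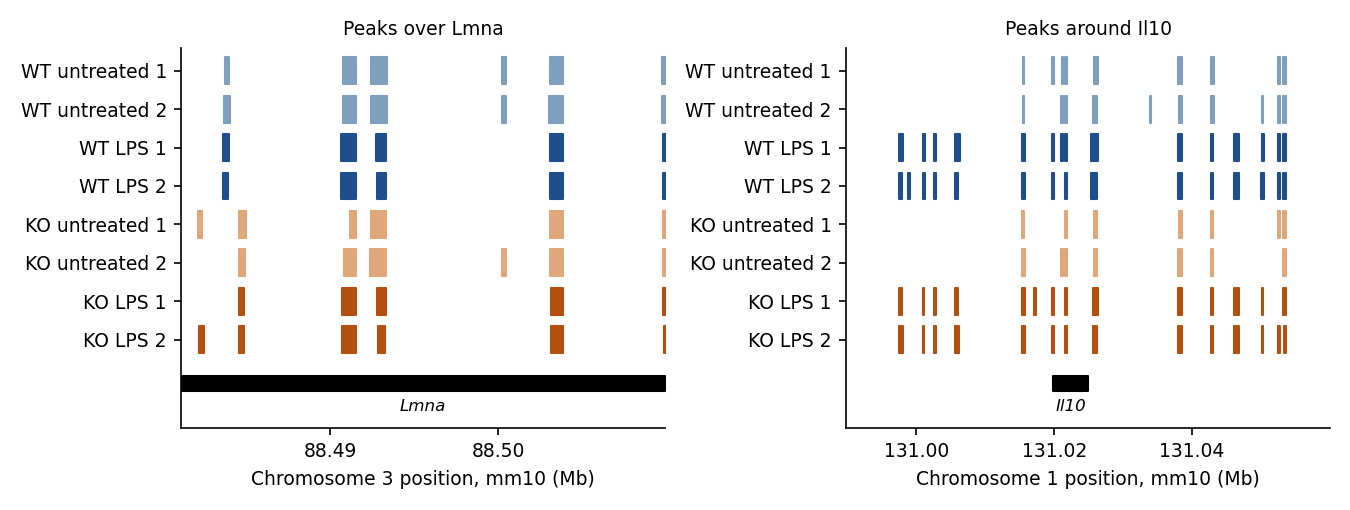
Called peaks in each of the 8 libraries along Lmna (left, chromosome 3) and around Il10 (right, chromosome 1), with mm10 position in Mb on the horizontal axis and the gene span as a black bar. At the left of the Lmna panel, 1 peak is in all 4 WT libraries and another in all 4 KO libraries; at the left of the Il10 panel, the peak starting at 130997422 is in the 4 LPS libraries alone.

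KO macrophages had fewer, narrower peaks than WT macrophages, with the same recovered background. The KO lists held 46764.5 ± 2289 peaks (SD, n = 4) and the WT lists 56028 ± 2555 (SD, n = 4), and every KO list was shorter than every WT list. Covered length was 18.99 Mb in KO and 23.97 Mb in WT, median peak width 368 bp and 383 bp, and the share of peaks at gene ends 23.6% ± 0.827 and 21.1% ± 0.942 (SD, n = 4 each). Each of these 4 differences had an exact permutation p = 0.0556, the smallest the design allows, and an adjusted p = 0.102. The share of peaks in gene-poor windows was 6.89% in KO and 6.84% in WT (exact p = 0.444). LPS libraries had a lower share at gene ends than untreated libraries (21.6% against 23.01%) and a higher share in gene-poor windows (7.09% against 6.65%), each with exact p = 0.0556 and adjusted p = 0.102. Peak number was higher with LPS by 3050.5 in WT and 1574 in KO, a difference of -1476.5 between genotypes (exact p = 0.722), and by 2312 over both (exact p = 0.222). The last value was 1214 without WT LPS replicate 1 and 1257.5 without KO LPS replicate 1, each the mean of the differences within WT and within KO. The difference between genotypes turned to a positive value of at most 720.0 without WT LPS replicate 1 or KO LPS replicate 2.

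**Figure D2:**
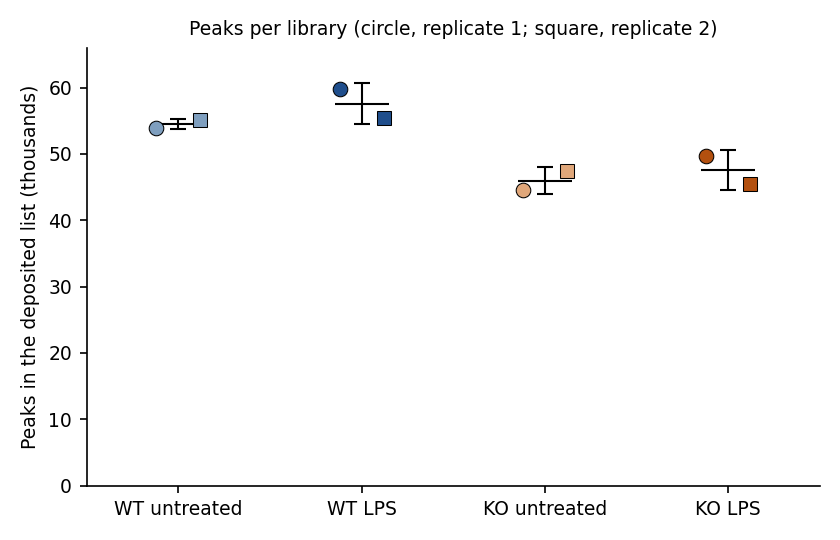
Peaks in each deposited list (vertical axis, in units of 1000 peaks) for the 4 groups; circles and squares are replicates 1 and 2, the long bar is the mean and the whiskers are 1 SD (n = 2). The 4 KO libraries lie between 44504 and 49661 peaks, below the 4 WT libraries at 53942 to 59750.

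In WT macrophages, LPS-gained regions included some of the strongest peaks of the LPS lists. The strongest lay 9.0 kb from Ier5, an immediate early gene, on chromosome 1 from 155108421 to 155108943, at percentile 97.2. Others among the 10 strongest lay 22.1 kb from Il10, an anti-inflammatory cytokine (percentile 91.9), 39.3 kb from Il1b, a pro-inflammatory cytokine (91.7), inside Tnip1, an inhibitor of NF-kB signalling (92.4), and inside Pfkfb3, a regulator of glycolysis (93.8). The rest of the 10 were assigned to Rbbp8, Slco3a1, Ints3, Fcrlb and Rap1gap2. The strongest lost regions were weaker, at percentiles of 68.7 to 86.4, and included 1 on chromosome 1 from 131096789 to 131097247 at the end of Mapkapk2, a kinase downstream of p38, and others near Hspa9, Pex5, Tmem86a, Rab31, Gfra2, Tmprss7, Dmxl1, Dido1 and Plekho2. In all, 7769 regions were gained and 4617 lost in WT, against 300 to 805 on either side in the other 2 divisions of the same 4 libraries. Leaving out a library leaves fewer that must agree, and the gained count then reached 12048 without WT LPS replicate 2, while the lost count reached 5894 to 7690 over the 4 libraries, over 1.5 times its value without either untreated replicate or WT LPS replicate 1.

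Interferon response genes stood out among the genes near LPS-gained regions in WT. Of the 41 list members with any region, 24 had a gained region, against a mean of 12.8 in matched random lists (permutation p = 0.0002, the smallest the random lists can give; adjusted p = 0.0028). Ddx58, a sensor of viral RNA, had 3 gained of 8 regions. Among inflammatory cytokines and enzymes, 18 of 30 genes had a gained region against 13.4 in random lists (adjusted permutation p = 0.438), with 6 of 11 regions gained at the chemokine gene Ccl5 and 5 of 7 at Il6. The NF-kB list had 19 of 29 against 15.6 (adjusted permutation p = 0.466), with 7 of 24 at Nfkb1 and 6 of 9 at Birc3, an inhibitor of apoptosis. Macrophage identity genes had 9 of 29 against 14.3 (adjusted permutation p = 0.328), and alternative activation and scavenging genes 4 of 17 against 6.73 (adjusted p = 0.466). With a -log10 p of at least 20, macrophage identity genes passed, at 6 of 29 against 13.4 (adjusted permutation p = 0.0280). Cell cycle genes had 5 of 26 against 6.60, nuclear envelope and lamina genes 7 of 23 against 6.35, B cell markers 3 of 7 against 1.498, T and NK cell markers 1 of 13 against 2.20, and neutrophil markers 3 of 12 against 1.85. Dendritic cell markers had 6 of 11 against 3.79, erythroid and megakaryocyte markers 0 of 8 against 1.06, stromal and endothelial markers 7 of 14 against 4.37, and stem and progenitor markers 5 of 12 against 3.73. None of these 9 lists passed the threshold (adjusted p of 0.466 to 0.916). No list passed among lost regions, where 1 had an unadjusted p under 0.05. That was the interferon response, with 4 of 41 against 9.44 (permutation p = 0.0400, adjusted p = 0.560), which passed with equal numbers of peaks at 2 of 41 against 9.40 (adjusted p = 0.0280).

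**Figure D3:**
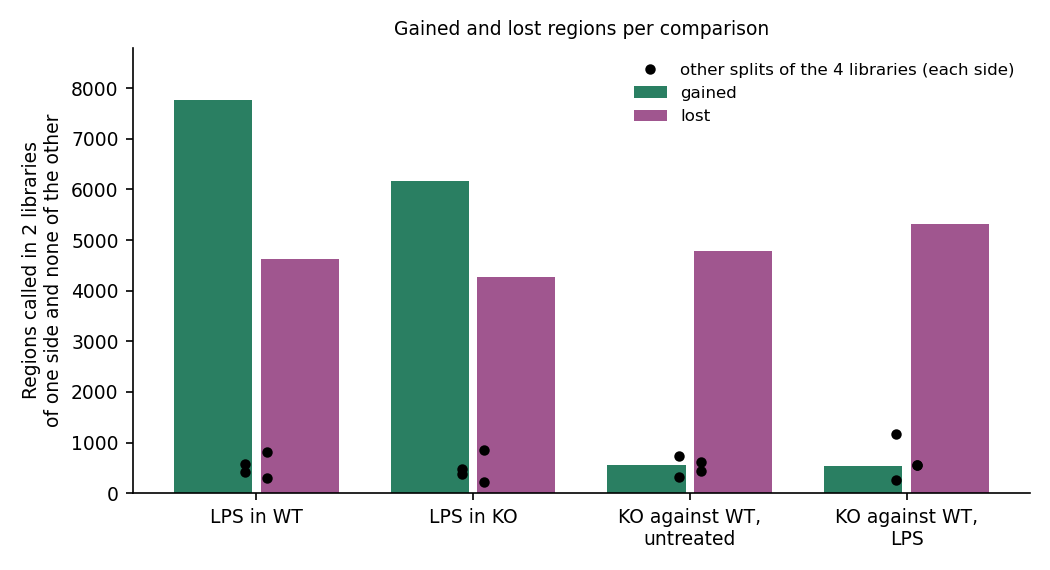
Regions called in both libraries of one group and neither of the other (vertical axis, number of regions) for the 4 pairwise comparisons; bars are gained and lost regions, and dots are the sides of the other 2 divisions of the same 4 libraries. LPS bars stand at 4269 to 7769 regions, while the KO-gained bars of 564 and 546 lie among their dots.

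In KO macrophages, the Ier5, Slco3a1, Rbbp8, Il10 and Rap1gap2 regions were again among the 10 strongest gained with LPS, at percentiles of 91.6 to 95.6. The other 5 lay near or inside Alcam, an adhesion molecule, Abi1, Ube2z, St3gal1 and Ktn1, and those near Abi1, Ube2z, St3gal1 and Ktn1 were called in all 4 WT libraries, untreated ones included. The strongest lost regions, at percentiles of 71.3 to 85.3, included 1 inside Csf1r, the receptor of the growth factor M-CSF (chromosome 18, 61120481 to 61120952), 1 inside Acod1, the enzyme that makes itaconate, and 1 located 20.4 kb from Cebpa, a myeloid transcription factor. The other 7 were assigned to Rpl3, Fgd4, Plekhm1, Itprid2, Tsc22d3, Umad1 and Nelfa. Myc, a transcription factor of growth and division, had 6 of its 10 regions lost, the most of any gene in its list. There were 6161 gained and 4269 lost regions, against 221 to 849 on either side in the other 2 divisions. The gained count reached 9870 without KO LPS replicate 2, and the lost count 7613 at most, with a move of over 1.5 times without KO untreated replicate 1 or KO LPS replicate 1.

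Of the 14 lists, 3 passed among LPS-gained regions in KO. Interferon response genes had a gained region in 22 of 41 against 10.9 in random lists (adjusted permutation p = 0.0028), with 4 of 8 regions gained at Trim30a and 3 of 5 at Ifi44. Inflammatory cytokines and enzymes had 20 of 30 against 11.6 (adjusted permutation p = 0.0056), with 6 of 15 at Il10, 4 of 11 at Ccl5 and 3 of 10 at Nos2, the inducible nitric oxide synthase. Macrophage identity genes had gained regions less often than random lists, 6 of 29 against 12.7 (adjusted permutation p = 0.0336), and the 4 with the most were Msr1, Runx1, Cybb and Cebpb. The macrophage identity call ended with equal numbers of peaks (0.564 of the random mean, adjusted permutation p = 0.210) and in 4 more settings, and the inflammatory call ended with genes within 20 kb (adjusted p = 0.0616) and with a -log10 p of at least 20 (adjusted p = 0.1204). Without KO untreated replicate 1 the macrophage identity call also ended, with adjusted p up to 0.0882. No list passed among lost regions, and none there had an unadjusted p under 0.05. The inflammatory list passed in KO and not in WT, but the difference between the genotypes was not tested. That contrast also depended on the libraries used. Without WT LPS replicate 1, 23 of 30 of its genes had a gained region in WT, against 15.7 in random lists.

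**Figure D4:**
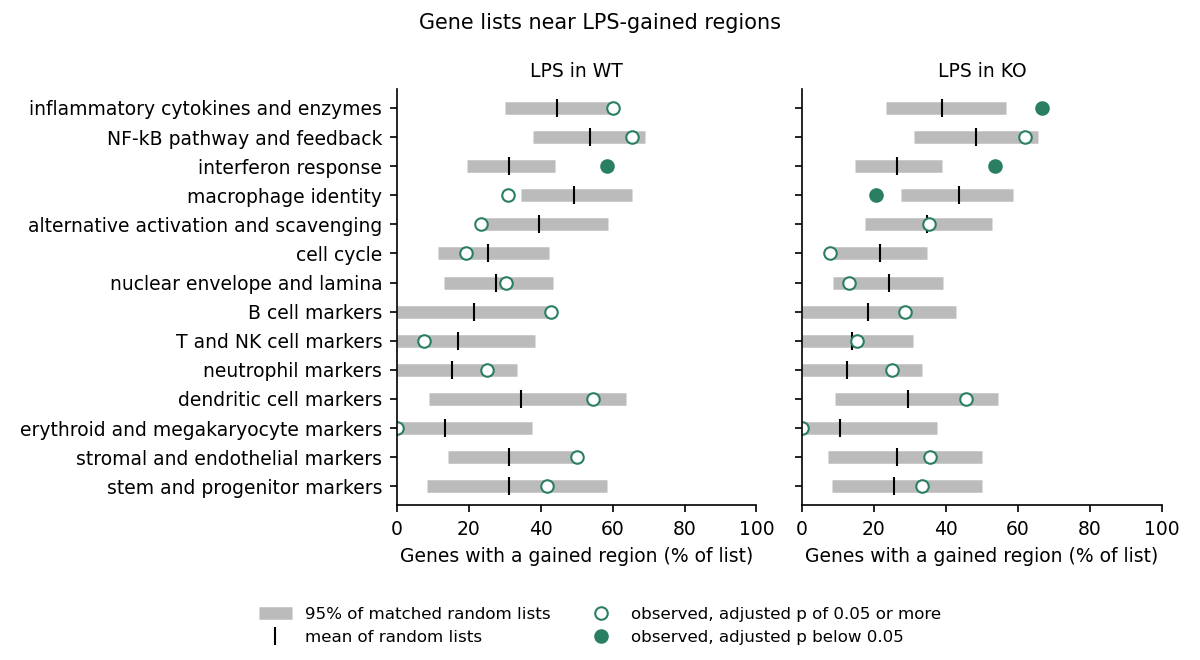
Share of each list's genes with an LPS-gained region (horizontal axis, percent of list members with any region) in WT (left) and KO (right); circles are the observed shares, filled where the adjusted p was below 0.05, and grey bars and ticks show the middle 95% and the mean of matched random lists. The interferon response lies to the right of its grey bar in both genotypes, at 24 and 22 of 41 genes.

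The LPS response was set side by side in the 2 genotypes. Both genotypes gained 3720 of the same regions, 5.97 times the 624 that independent lists would share, and lost 1375 of the same, 5.35 times the 257. Expected counts for independent lists, here and below, are taken over all 76751 regions. These include the 30960 called in all 8 libraries, which can be neither gained nor lost, so without them the expected counts would be higher. The 3720 gained and 1375 lost regions are those that divide all 4 LPS from all 4 untreated libraries. The 10 strongest gained ones lay near or inside Ier5, Slco3a1, Rbbp8, Il10, Rap1gap2, Fcrlb, Ints3, Denr, Alpk2 and Fpr1, a receptor for bacterial formyl peptides. The 10 strongest lost ones lay near or inside Mapkapk2, Tmem86a, Pex5, Tmprss7, Gfra2, Rab31, Dmxl1, Plekho2, B4galt1 and Ccl4, a chemokine gene. Of the WT LPS-gained regions, 4234 (54.5%) were called in both KO LPS libraries and 1918 (24.7%) in neither. Of the KO LPS-gained regions, 5337 (86.6%) were called in both WT LPS libraries and 311 (5.05%) in neither. With equal numbers of peaks per library this contrast was gone, at 73.8% and 73.9%, and leaving out an LPS library of either genotype moved these shares to between 38.4 and 68.4% and between 70.8 and 92.5%. Part of this movement is by construction. Without a library of the other genotype, fewer libraries must call a region, which raises the share. Without a library of the same genotype, the gained class is wider. No list passed among the 3720 gained regions, where 3 had an unadjusted p under 0.05. These were inflammatory cytokines and enzymes (14 of 30 against 7.88, adjusted permutation p = 0.126), the NF-kB pathway (16 of 29 against 10.0, adjusted p = 0.126) and the cell cycle (0 of 26 against 3.57, adjusted p = 0.126). The inflammatory and interferon lists passed with equal numbers of peaks, each with adjusted permutation p = 0.0070.

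In untreated macrophages, the comparison of KO with WT asked what loss of Lamin-A does before any stimulus. KO-gained regions lay 23018 bp from Cd5l, which encodes a secreted macrophage protein (chromosome 3, 87334648 to 87335050, percentile 68.7), inside Dclk2 (percentile 68.2), inside Pik3r2, a regulatory subunit of PI3 kinase (54.2), and inside Lmna (49.4), with the other 6 of the 10 strongest assigned to Cdca7l, Slc2a13, Trafd1, Coa4, Selenbp2 and Cyp2b19. The strongest KO-lost region lay 2.7 kb from Mfng, a glycosyltransferase that modifies Notch (percentile 91.2), and others lay inside Fcrl1, near Tbx5, inside Sh3d19, and near Tnfsf8, the CD30 ligand. The rest were assigned to Fhdc1, Trim69, Ktn1, Galnt6 and Pls3. The Cd5l, Dclk2, Lmna, Fcrl1, Sh3d19 and Fhdc1 regions lie within 5 Mb of the targeted gene or in it, where linked strain variants are not excluded. There were 564 gained and 4775 lost regions, while the other 2 divisions gave 314 to 743 on either side, so the gained count was within their range. There were 1458 gained and 1598 lost with equal numbers of peaks, against 529 to 616 in the other divisions. Equal numbers drop the weakest peaks of the longer WT lists. Regions that the deposited WT lists hold can then count as gained, which divisions that mix the genotypes cannot show. No gene list passed in either direction, and none had an unadjusted p under 0.05; among lost regions, Irf8 and Runx1, transcription factors of myeloid cells, had 3 each, of 15 and 28. With equal numbers of peaks, the whole macrophage identity list had 2 lost regions over 2 genes, against 18 over 12 as deposited. Leaving out any of the 4 libraries raised the gained count, to 986 to 2183, and the lost count reached 6946 to 8922, a move of over 1.5 times without either WT replicate or KO untreated replicate 2.

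After LPS, KO-gained regions again included those near Dclk2, Cd5l and Pik3r2, at percentiles of 55.7 to 60.1, and the strongest was inside Aopep (61.5). The others were assigned to Fbln1, Fbxo36, Plpp3, Creb5, Gng3 and Fam110c. The strongest KO-lost regions were inside Babam2 (chromosome 5, 32077092 to 32077587, percentile 62.2) and 2.3 kb from Tbx5 (61.1), followed by Snd1, Baz2b, Scaper, Snrpf, Btbd8, Cep43, Tubb1 and Dhx40. Il6 had 4 of its 7 regions lost in KO, Il1b 3 of 12, Myc 5 of 10 and Fcgr1, a receptor for immunoglobulin G, 3 of 12. Most such losses went with the lengths of the lists. With equal numbers of peaks, lost regions fell from 24 to 6 over the inflammatory list and from 13 to 3 over macrophage identity genes. Over cell cycle genes, which include Myc, they fell from 13 to 2. No gene list passed in either direction; the only unadjusted p under 0.05 was that of alternative activation and scavenging genes among lost regions, with 1 of 17 against 5.75 (permutation p = 0.0114, adjusted p = 0.160). In all, 546 regions were gained and 5327 lost, and the other 2 divisions gave 262 to 1174. Equal numbers of peaks gave 1453 gained and 1712 lost, against 585 to 696 in the other divisions. Here too, the gained count can include regions that the deposited WT lists hold. Without any 1 of the 4 libraries the gained count was 920 to 2124, and the lost count was 7100 to 11134, the latter a move of over 1.5 times except without KO LPS replicate 2.

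Across both treatments, 52 regions were called in all 4 KO and no WT library, and 661 in all 4 WT and no KO library. The gained ones included those of Dclk2, Cd5l, Pik3r2 and Lmna, and 1 inside Irf8 (chromosome 8, 120741024 to 120741348), with Fcrl1, Gng3, Gm52612, Klb and Gm21149 completing the 10. The strongest lost ones were near Tbx5, a cardiac transcription factor, and inside Fcrl1 and Sh3d19, followed by Pls3, Sap30bp, Car2, Far1, Cd5l, Alpk2 and Fosb, an AP-1 subunit. The Dclk2, Cd5l, Fcrl1, Lmna and Sh3d19 regions again lie in or within 5 Mb of the targeted gene. Independent untreated and LPS comparisons would share 4.01 gained and 331 lost regions, but chance groupings of the libraries also share regions. Single sides of the other 33 divisions of the 8 libraries held 0 to 260 regions, the highest being sides with 3 of the longer WT lists, while sides with 3 KO libraries held 0 to 30. With equal numbers of peaks the counts were 171 gained and 116 lost, against 4 to 97 on single sides of those 33 divisions. These 171 can likewise include regions that the deposited WT lists hold. No gene list passed, and none had an unadjusted p under 0.05. The gained count was over 1.5 times higher without WT LPS replicate 1, KO untreated replicate 1 or KO LPS replicate 2 (61 to 90 over all 8 libraries), and the lost count without WT LPS replicate 2, KO untreated replicate 2 or KO LPS replicate 1 (824 to 1208).

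The region assigned to Pls3 lies in the span of Dxz4, 1 of 3 loci of the X chromosome linked to X inactivation, which were chosen after their values were seen. Together Firre (50563120 to 50635321), Dxz4 (75725458 to 75764699) and Xist (103460373 to 103483233) held 29 regions, and WT libraries called 25 to 28 of them while each KO library called 1. Of 24 regions called in all 4 WT libraries, 23 were in no KO library (95.8%, exact 95% interval 78.9 to 99.9%). The first 2 Mb of the Y chromosome held 6 regions, of which KO libraries called 5 or 6 and WT libraries 2 to 4. Of all 25 Y regions, 1 was called in all 4 KO and no WT library. Another 1, outside the first 2 Mb, was called in all 4 WT and no KO library. The differences at the 3 X loci and in the first 2 Mb of Y run along with genotype in every library and so stand beside each KO comparison. On chromosomes 1 to 19 alone, 51 regions were in all 4 KO and no WT library and 620 in all 4 WT and no KO library.

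**Figure D5:**
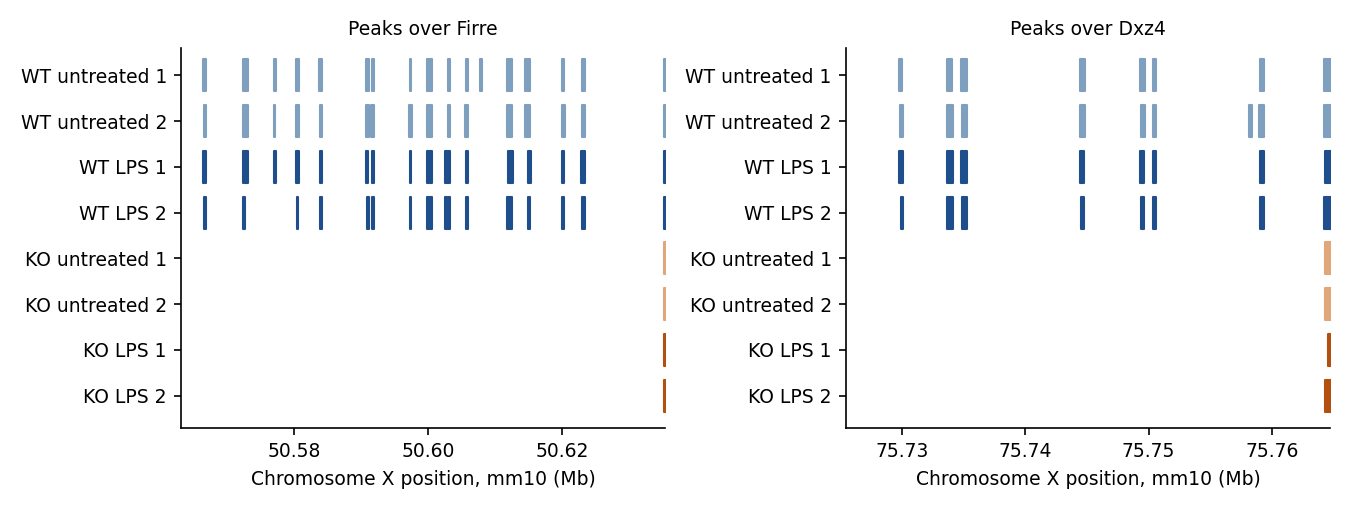
Called peaks in each of the 8 libraries along Firre (left) and Dxz4 (right), with mm10 position on chromosome X in Mb on the horizontal axis. Peaks fill the 4 WT tracks, while the KO tracks hold only the peak at the right edge of each panel, which at Firre has its summit outside the gene span.

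Gained and lost regions were rarer at gene ends than regions called in all libraries. In WT, 5.26% of LPS-gained and 10.3% of LPS-lost regions were at gene ends, against 25.3% of shared regions (for the lost ones, odds ratio 0.338, Fisher's exact test, adjusted p = 4.7e-133). Regions from the other divisions of the same libraries were also rarer at gene ends, at 11.1 to 13.5% over the 4 comparisons. LPS-gained regions were more frequent in gene-poor windows, at 9.89% in WT and 10.6% in KO, against 6.23% and 6.11% of shared regions (odds ratios 1.65 and 1.83, Fisher's exact test, adjusted p = 1.55e-28 and 6.22e-34). So were LPS-lost regions, at 8.64% in WT and 8.18% in KO (odds ratios 1.42 and 1.37, Fisher's exact test, adjusted p = 2.24e-09 and 7.29e-07). Directly compared, LPS-gained against LPS-lost odds ratios were 1.16 in WT and 1.34 in KO (Fisher's exact test, adjusted p = 0.0330 and 5.81e-05). The WT one was 1.12 to 1.19 with 1 library left out. KO-gained regions had a share in gene-poor windows of 15.9% after LPS against 6.80% of shared regions (odds ratio 2.60, Fisher's exact test, adjusted p = 6.2e-13) and 10.8% without LPS against 6.31% (odds ratio 1.80, adjusted p = 7.17e-05). KO-lost regions had 7.26% after LPS (odds ratio 1.07, Fisher's exact test, adjusted p = 0.203) and 7.39% without (odds ratio 1.19, adjusted p = 0.00504), and regions from the other divisions 6.57 to 8.74%. Directly compared, KO-gained exceeded KO-lost regions in gene-poor windows after LPS (odds ratio 2.42, Fisher's exact test, adjusted p = 6.29e-10) and without it (1.52, adjusted p = 0.0117), and with equal numbers of peaks the odds ratios were 1.74 (adjusted p = 3.15e-05) and 1.26 (adjusted p = 0.0966). The untreated call also ended with windows around summits (1.10, Fisher's exact test, adjusted p = 0.483), with a -log10 p of at least 20 (1.15, adjusted p = 0.455) and without WT untreated replicate 2 (adjusted p up to 0.185). At gene ends, the KO-gained against KO-lost comparison turned with the setting: the odds ratio without LPS was 0.710 (Fisher's exact test, adjusted p = 0.0715) as deposited and 1.33 (adjusted p = 0.0463) with equal numbers of peaks, and after LPS it was 0.865 (adjusted p = 0.463) and 1.06 (adjusted p = 0.663). Without LPS and after it, the same odds ratio was 2.16 and 2.53 with windows of 100 bp either side of summits (Fisher's exact test, adjusted p = 1.4e-13 and 9.15e-19) and 0.656 and 0.676 with 50% cover (adjusted p = 0.0134 and 0.0203). It was 0.522 without LPS with a -log10 p of at least 20 (Fisher's exact test, adjusted p = 0.00159), so no direction holds.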

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

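The tests of technical and biological explanations in this part, and the comparison with other divisions with equal numbers of peaks, were chosen only after the results were seen; the count over the 35 divisions was planned.

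At 9 regions the calls with LPS went opposite ways in the genotypes: the region was gained in WT and lost in KO. They include regions inside Nfkbid, which encodes an atypical inhibitor of NF-kB, and inside Rbm47, Zfp777 and Asap1, and near Mfsd6 and Tha1. At another 7 regions it was lost in WT and gained in KO, among them regions inside Insig2, Cry1 and Riok2 and near Hmcn1 and Srcin1. These genes were named after their values were seen, and the difference between genotypes was not tested at any of them. These 16 regions are no more than arbitrary divisions give: the median over the 33 divisions of the 8 libraries other than LPS and genotype was 43. Independent lists would give 432 and 371, and all 16 lay at or below percentile 30.2.

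The X chromosome loci Firre, Dxz4 and Xist were called in WT and, apart from 1 region of Dxz4, not in KO. The 6 regions in the first 2 Mb of the Y chromosome were together called more often in KO, with 23 calls against 13 in WT. Over all 25 Y regions, 1 was called in all 4 KO and no WT library, and 1 in all 4 WT and no KO library. Of the 29 regions at the 3 loci, 96.6% were called in some WT library and no KO library, in line with more female cells in the WT libraries. Of the 24 regions at these loci called in all 4 WT libraries, 23 (95.8%) were in no KO library. Shorter KO lists as the whole cause are argued against, since 2.73% of autosomal regions of the same strength were called in all 4 WT and no KO library. Loss of Lamin-A and sex of the animals cannot be told apart here. The calls at the X loci and in the first 2 Mb of Y follow genotype in every library, and the labels give no sex. WT libraries also called 2 to 4 of the 6 regions in the first 2 Mb of Y, so cells with a Y chromosome may be present in both genotypes.

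KO-gained or KO-lost regions were more frequent within 5 Mb of Lmna than on the other autosomes, at 11 of 495 regions against 610 of 71393 (odds ratio 2.64, 95% interval 1.44 to 4.82, Fisher's exact test, adjusted p = 0.0103). An interval that changes in any comparison is argued against by the LPS regions, whose odds ratio there was 0.593. Strain variants linked to the targeted allele are a candidate explanation, since the odds ratio of KO-gained regions alone was 14.9 within 5 Mb (95% interval 5.31 to 41.9, Fisher's exact test, adjusted p = 0.00173), 5.90 from 5 to 20 Mb (1.82 to 19.1, adjusted p = 0.0309) and 3.03 beyond (1.08 to 8.47, adjusted p = 0.0779), on 4, 3 and 4 regions, and 12 of the 52 KO-gained regions, the Lmna one included, were on chromosome 3. KO-lost odds ratios did not fall steadily with distance, at 1.78 (0.840 to 3.77), 0.802 (0.358 to 1.80) and 1.82 (1.29 to 2.56), nor did those of both directions together, at 1.13 (0.583 to 2.19) from 5 to 20 Mb and 1.90 (1.37 to 2.63) beyond. These intervals overlap and 11 of the other 240 windows of 10 Mb had a higher share, so linked variants cannot be told apart from a difference along the chromosome or uneven shares between windows. The regions of Dclk2, Cd5l and Fcrl1 named above are among those counted within 5 Mb. The 7 regions of Lmna itself were left out of these counts and odds ratios. The p-values there thus do not test a pattern apart from the regions already seen.

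The KO lists held fewer peaks, with 8.47 lost for each gained region in untreated cells. Fewer reads given to the peak caller are argued against by the recovered background, which ranged over the 8 libraries by 9.7e-06% of its mean; it says nothing of the share of reads in peaks. Lower enrichment over background in the KO libraries may account for it, since 0.586% of untreated KO-lost regions lay above percentile 50 of the WT lists, against 5.35% of LPS-lost regions. The median fold enrichment of called peaks was similar, at 6.96 to 7.79 in the KO lists and 7.08 to 7.74 in the WT lists. That median leaves out regions that were not called, so it does not decide the point. Closing of weak regions through loss of Lamin-A would give the same ratio of 8.47, so it cannot be told apart from lower enrichment without read counts over fixed regions.

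Of the 35 divisions of the 8 libraries into 4 and 4, 1 gave as many dividing regions as LPS against untreated, which was that division itself with 5095 regions, the next highest being 713. This argues against chance for LPS but does not exclude it. A share of 1 of 35 is the smallest that this count can give, and the labels do not say whether replicates came from different animals. KO against WT gave 713 regions, and 2 of 35 divisions gave as many, so that chance is not excluded by this count; the other was the LPS division with 5095, which points to the treatment structure of the samples, and the other 33 gave at most 269. KO against WT with equal numbers of peaks gave 287 regions, and apart from the LPS division the highest other count was 146. The 287 can include regions held by the deposited WT lists, whose weakest peaks were dropped.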

How the results depend on the processing

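The -log10 p of at least 20, the assignment to gene spans and the direct comparison of gained with lost regions were chosen after seeing the data. Over settings other than leaving out a library, 376 results that answer a comparison kept their direction and their side of the threshold, or a count within 1.5 times, and so did 36 counts of named regions; 24 moved, 10 became weaker, 3 stronger and 7 reversed. The cause of a change was not tested unless given. The exact tests between libraries cannot reach p below 0.05 in any setting, so only their direction could change. Named regions are the strongest of their own class, so stricter cut-offs could hardly remove them. With a replicate block the differences in peak number stayed at -9264 for KO minus WT (exact p = 0.125, the smallest possible there), 2312 for LPS minus untreated (exact p = 0.375) and -1476.5 for the interaction (exact p = 0.667). Replicate numbers did not pair libraries between groups (6 correlations of -0.00693 to 0.00744). Restriction to chromosomes 1 to 19 changed no call. Equal numbers of peaks give no value for peak number, and the motif and GC settings were not run for want of a genome sequence. No peak on the flat background had a pileup below 23, which limits what depth can show.

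With equal numbers of peaks, which removes the length of a list by construction, covered length with LPS minus untreated was -0.348 Mb. KO-gained and KO-lost regions numbered 1458 and 1598 untreated, 1453 and 1712 after LPS, and 171 and 116 over both treatments. The KO-gained ones can include regions dropped from the longer WT lists. Regions lost with LPS in both genotypes numbered 2100, and the shares of LPS-gained regions called in the other genotype were 73.8% for WT and 73.9% for KO. KO-gained against KO-lost regions had gene-end odds ratios of 1.33 untreated and 1.06 after LPS, and a gene-poor odds ratio of 1.26 untreated. The lists passing were 1 among WT LPS-lost and 2 among regions gained in both genotypes, and the KO macrophage identity ratio to random was 0.564.

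The macrophage identity ratio in KO was 0.474 (adjusted permutation p = 0.0523) with a -log10 p of at least 10, 0.533 (0.0887) with 50% cover, 0.607 (0.526) within 20 kb and 0.695 (0.604) with a -log10 p of at least 20. With 50% cover, 1 list passed among regions gained in both genotypes, and KO-gained against KO-lost gene-end odds ratios were 0.656 untreated and 0.676 after LPS. With windows of 100 bp either side of summits, KO-gained regions numbered 868 untreated, 846 after LPS and 89 over both, and 84.0% of KO LPS-gained regions were called in WT. There the gene-end odds ratios of KO-gained against KO-lost regions were 2.16 and 2.53, and the untreated gene-poor one was 1.10. Within 20 kb, 1 list passed among KO LPS-gained regions, and the inflammatory ratio was 1.72 (adjusted permutation p = 0.0616). With a -log10 p of at least 20, covered length with LPS was -0.133 Mb, the gene-poor share KO minus WT was -0.0734, and KO-gained regions after LPS numbered 359. In that setting the shares called in the other genotype were 56.7% and 87.8%, and the untreated KO-gained against KO-lost odds ratios were 0.522 at gene ends and 1.15 in gene-poor windows. The lists passing were then 2 for WT LPS-gained, 1 for KO LPS-gained and 2 for both, with an inflammatory ratio in KO of 1.65 (adjusted permutation p = 0.1204).

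Leaving out each library in turn, 301 results kept their direction and side of the threshold, 45 moved, 6 reversed, 5 became stronger and 3 weaker. For the exact tests between libraries, only the direction could change here too. Counts rise by construction, since fewer libraries must agree. Differences between libraries are means of those within the strata, a weighting set after the data were seen, because pooled means mix in the other factor once a library is left out (peak number with LPS was then -86.9 to 4682). Peak number with LPS ranged from 1214 (without WT LPS replicate 1) to 3411, the interaction from -3673 to 720.0 (positive without WT LPS replicate 1 or KO LPS replicate 2), covered length with LPS from -0.282 to 0.828 Mb (negative without WT LPS replicate 1 or KO LPS replicate 1), and the gene-poor share KO minus WT from 0.0147 to 0.0854. Gained and lost regions ranged from 9012 to 12048 and 5894 to 7690 for LPS in WT, 7110 to 9870 and 5226 to 7613 for LPS in KO, 986 to 2183 and 6946 to 8922 for KO untreated, and 920 to 2124 and 7100 to 11134 for KO after LPS. LPS-lost regions over both genotypes ranged from 1429 to 2099 (highest without KO untreated replicate 1), and KO-gained and KO-lost over both treatments from 61 to 90 and 824 to 1208. Shares called in the other genotype ranged from 38.4 to 68.4% for WT and from 70.8 to 92.5% for KO, in part by construction, since fewer libraries must agree. The gained against lost gene-poor odds ratio ranged from 1.12 to 1.19 for LPS in WT and from 1.19 to 1.61 for KO untreated (both weaker without WT untreated replicate 2). The gene-end one ranged from 0.689 to 0.920 for KO untreated (stronger without WT untreated replicate 1 or KO untreated replicate 1) and from 0.753 to 1.16 for KO after LPS (changed without WT LPS replicate 2, KO LPS replicate 1 or KO LPS replicate 2). KO-lost against shared regions after LPS ranged from 1.07 to 1.12 in gene-poor windows (stronger without either WT LPS replicate). Lists passing ranged from 1 to 2 for WT LPS-gained regions (2 without either WT LPS replicate), 0 to 1 for WT LPS-lost and KO-lost after LPS (1 without WT LPS replicate 1), 2 to 5 for KO LPS-gained (5 without KO LPS replicate 2), 0 to 1 for KO LPS-lost (1 without KO LPS replicate 1) and 0 to 2 for those gained in both genotypes (changed without WT LPS replicate 2 or KO LPS replicate 2), and the macrophage identity ratio from 0.354 to 0.570.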

Other observations

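The genes in this part were chosen after their values were seen, and no test was run on them. Met, the receptor of hepatocyte growth factor, had the most LPS-gained regions of any gene, with 11 of its 21 regions in WT, 10 in KO and 9 in both. Rcl1 followed with 9 of 15 in WT and 9 in KO, and Hif1a, a transcription factor of the hypoxia response, had 5 of 12 gained in both genotypes, as did Irak3, a negative regulator of Toll-like receptor signalling, with 5 of 18. Among lost regions, Gpr183, a receptor for oxysterols, had 4 of 10 lost with LPS in both genotypes, and Gpr34 had 5 of 6 lost in WT.

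The WT LPS-lost regions were called in both untreated KO libraries in 1640 cases (35.5%) and in neither in 1690 (36.6%). The KO LPS-lost regions were called in both untreated WT libraries in 3720 cases (87.1%). With equal numbers of peaks these shares called in both were 61.0% and 72.7%.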
